A study of Scyliorhinus canicula with 15 samples.

How the data were processed

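RNA sequencing profiled 5 oral compartments (SL, ET, LT, TTJ and BHTB), which the series assigns to the dental lamina, of the small-spotted catshark, Scyliorhinus canicula, with 3 libraries each. Per the labels' protocols, tissue came from 9 embryos, given as stage 33, 34 or 33/34 in different labels, and RNA samples with an integrity number above 8.0 were used. Libraries were unstranded, made with Illumina's TruSeq kit and sequenced as paired reads in 1 pooled lane, giving 132470224 reads with a mean length of 93 bases, per the labels' protocols. A kit without strand information cannot tell a gene's reads from those of an overlapping gene on the opposite strand.

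The authors deposited 1 RSEM table per library, holding values for 381441 isoforms of a de novo assembly. Per the submitters' processing notes, Bowtie2 and RSEM were used. Their versions, the read trimming and the assembly settings are not given in the sources used here. Per the file headers, each table gives an expected count per isoform, which is RSEM's estimate of the reads or read pairs an isoform produced and need not be whole. The deposited expected counts had no decimal part in 91.8% of values, those at 0 included. The deposited tables also give TPM and FPKM, the authors' RSEM values normalised to length and depth, and the isoform percent of each gene. The TPM, FPKM and isoform percent values were not used in any test. A deposited count matrix of the whole series held the same expected counts, with 0 values that differed from the tables of the libraries. The genome-guided assembly that the series design mentions was not used here.

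The isoforms belonged to 342966 gene identifiers, 93.3% of them with 1 isoform, and contigs were 161 to 17571 bases long with a median of 342. A de novo assembly can split 1 gene over several identifiers or join copies of a gene, so an identifier is not a gene locus. None of the identifiers (0) matched the table of 29227 genes of assembly sScyCan1.1, and the files do not pair identifiers with gene names. The gene lists fixed for this tissue could therefore not be tested, and no coordinates are given. No genome sequence was used here.

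Expected counts were summed per gene identifier and rounded to whole numbers. They came to 122388998 counts. Whether RSEM counted read pairs or single reads is not given in the sources used here. The stated reads and their mean length give the stated 12.32 gigabases, so the stated number is of single reads. The counts came to 92.4% of it, more than read pairs alone could give, so they appear to be of single reads. Both reads of a pair would then be counted, so counting intervals may be too narrow and floors too low. Library totals ranged from 4322260 (TTJ replicate 1) to 15566444 (ET replicate 3), a 3.6-fold range. Genes with enough counts were kept with edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 33550 identifiers (9.78%) holding 96.3% to 97.9% of each library's counts. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion and 5 compartment means was fitted to the 15 libraries in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with 10 residual degrees of freedom. The common biological coefficient of variation was 0.25. Tests were an F-test among compartments, each compartment against the mean of the other 4, and pairs of compartments, with Benjamini-Hochberg adjustment over genes and calls at an adjusted p under 0.05. Log2 differences carry a standard error computed as their size divided by the square root of F. CPM values are the counts divided by the TMM-scaled library size, in the usual CPM unit, and log2 CPM for principal components used a prior count of 2. A gene counted as highest in a compartment when it exceeded each of the other 4 in its own adjusted test.

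The rule for named identifiers was fixed before the data were examined. So were the tests of any difference and of each compartment against the mean of the others. The pairs described in the text and the genes highest in a compartment were also fixed, as were the alternatives except thinning. The pair patterns, the counts of genes below each other compartment and the shares of highest and lowest means were not part of that plan. The closing section says which of its own tests were chosen later. For identifiers without gene names, the naming rule takes the 2 with the largest rise and the 2 with the largest fall in each comparison. Candidates had to be called, with a mean of at least 5 CPM over the 15 libraries and no overlap of single libraries between the sides compared. Where a side had 0 counts, the fold of the mean CPM was bounded with 3 counts over the TMM-scaled sizes of the group. Where it had up to 3 counts, the ratio carries a 95% exact counting interval.

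The replicate numbers come from the sample titles, and the labels do not say what they stand for. Deviations of log2 CPM from the compartment mean were correlated between same-numbered libraries of different compartments, and 29 of 30 correlations were above 0.1 (range 0.077 to 0.608, mean 0.329). The exception was ET with BHTB for number 1, at 0.077. Differently numbered libraries had correlations of -0.341 to 0.087, and all 15 libraries correlated best with their own number. Deviations within a compartment cancel over its libraries, so the negative values follow from the positive same-number ones and add no separate evidence. By a rule of correlations above 0.1 in each pair, the numbers pair the libraries for each pair of compartments except ET with BHTB. The count from a fit with the number as a block is given beside each comparison described in the text where it moves the count by more than 1.5-fold. The source of the pairing is the data and not a label. Libraries of a compartment differed from each other by far more than sampling noise, with chi-square values per gene of 6.7 to 27.1, so none was counted as a duplicate.

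Tests were checked on simulated counts for 33550 genes with 200 genes changed in SL. For SL against the mean of the other 4, 38% of 2-fold and 81% of 4-fold changes were recovered, with 5.6% false among 126 calls. For SL against TTJ the shares were 25% and 66%, with 2.2% false, and for ET against SL 24% and 69%, with 6.1% false. The simulated libraries were independent, with no effect of the replicate number and with changes in SL only. These shares therefore describe that setting and need not hold for the real libraries. Alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling, no filter, the replicate block, isoform identifiers, a test against a fold change of 1.5, fits of the 2 compartments compared, and leaving out each library in turn. Thinning all libraries to 4322260 counts was added after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.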

Results

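Gene expression was measured by RNA sequencing in 5 tooth- and taste-bud-associated oral compartments of small-spotted catshark embryos, with 3 libraries per compartment. Per the labels, the epithelium was taken off the jaws and the soft tissue that remained, teeth included, was frozen, and they do not say how the compartments were separated, so which tissue each library holds is known only from its name. The labels give the compartments as SL, ET, LT, TTJ and BHTB and do not spell these names out. In published catshark work they are used for successional lamina, early tooth, late tooth, taste-tooth junction and basihyal taste buds. Total counts were 4961684, 5913266 and 7170329 in SL replicates 1 to 3 and 7182678, 10767000 and 15566444 in the ET libraries. The LT libraries held 10085093, 9916806 and 12926874 counts, the TTJ libraries 4322260, 7923703 and 4398510, and the BHTB libraries 4545564, 9311200 and 7397587. After thinning each library to 4322260 counts, the mean number of gene identifiers with at least 10 counts lay between 21610 in TTJ and 22224 in ET. The labels do not say that libraries of one compartment came from separate embryos, so each p-value measures the spread between these samples, which may be technical. Genes are named by their identifiers in the assembled transcriptome, for which the sources used here pair no gene names.

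Of the 5 compartments, ET and BHTB lay at opposite ends of the axis that held the most variance. The first principal component held 38.0% of the variance and ran from ET at -100.8 ± 8.83 to BHTB at 111.5 ± 10.6 (scores, SD, n = 3). On a scale from 0 at the ET mean to 1 at the BHTB mean, SL lay at 0.261 ± 0.055, LT at 0.359 ± 0.052 and TTJ at 0.754 ± 0.051. The second component held 14.2% of the variance and separated SL at 67.7 ± 32.4 from LT at -63.6 ± 21.2. The mean correlation of log2 CPM across genes was 0.83 between ET and BHTB libraries, against 0.938 to 0.958 within compartments. It was 0.926 between SL and ET, 0.929 between ET and LT, and 0.925 between TTJ and BHTB. Between SL and LT it was 0.906, so each of these correlated better with ET than with the other. The order on the first component is therefore not a single series of neighbours. Of 33550 genes tested, 10071 (30.02%) differed among the 5 compartments in edgeR's quasi-likelihood F-test at a Benjamini-Hochberg adjusted p under 0.05. The highest mean of these genes fell most often in BHTB (28.6%) and ET (25.4%), and the lowest mean in ET (34.5%) and BHTB (30.7%).

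**Figure D1:**
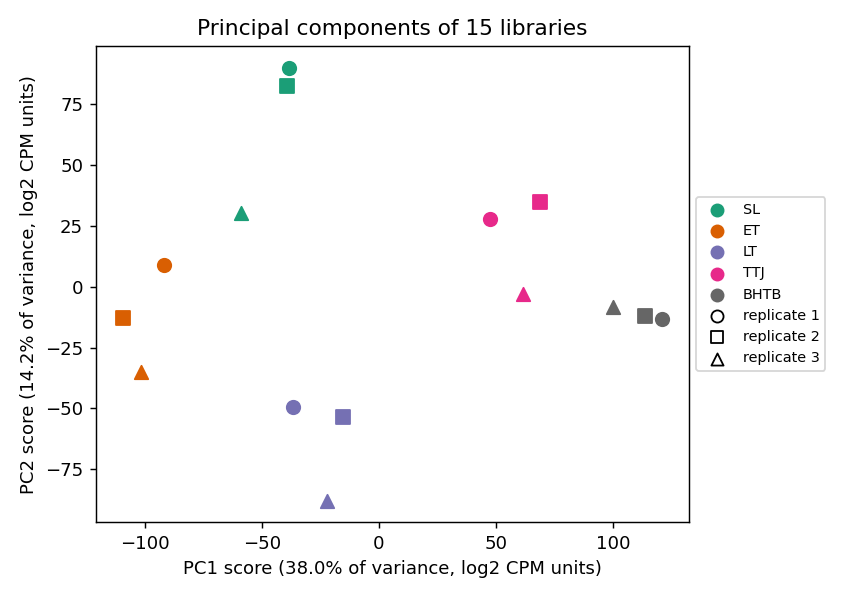
Each point is 1 of the 15 libraries, placed by its scores on the first and second principal components of log2 CPM, with color for the compartment and shape for the replicate number. ET and BHTB lie at opposite ends of the first axis (means -100.8 and 111.5), and SL and LT at opposite ends of the second (means 67.7 and -63.6).

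The most abundant transcripts were carried by all compartments. TRINITY_DN229_c0_g2, with a longest isoform of 16658 bases, held between 2.57% and 4.33% of the counts of each library and did not pass the test among compartments (edgeR adjusted p = 0.704). TRINITY_DN229_c0_g1 held 5.80% ± 1.35 of counts in ET and 4.28% ± 0.58 in LT, against 2.55% ± 0.447 in SL, 1.85% ± 0.537 in BHTB and 1.35% ± 0.535 in TTJ (SD, n = 3; edgeR F-test adjusted p = 0.000731). TRINITY_DN14_c0_g1 had the same order of compartments, from 3.20% ± 0.681 in ET to 0.75% ± 0.339 in TTJ (SD, n = 3; edgeR F-test adjusted p = 0.00283). The next most abundant, TRINITY_DN19_c0_g1, varied widely between libraries, from 0.187% to 4.35% of counts. Its SD exceeded its mean in LT (1.87% ± 2.15) and SL (1.21% ± 1.32), and it did not pass the test among compartments (edgeR F-test adjusted p = 0.923). Identifiers sharing a cluster number, such as both members of TRINITY_DN229, can share reads, so the division of counts between them is uncertain. These abundant identifiers were chosen after their values were seen.

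Which genes set SL apart was asked by comparing it with the mean of the other 4 compartments. In SL more of the called genes were higher than lower: 4036 genes passed the test, 2635 higher and 1401 lower. TRINITY_DN543_c0_g1 reached 1383 ± 426 CPM in SL (SD, n = 3) against 113 ± 218 CPM over the 12 other libraries, a log2 difference of 6.25 (SE 1.01; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00243). TRINITY_DN11505_c0_g1 reached 1122 ± 417 CPM against 101 ± 210 CPM (log2 difference 6.02, SE 0.735, edgeR adjusted p = 0.000424). The highest value of either in an ET or LT library was 6.65 CPM. In TTJ they differed between libraries: TRINITY_DN543_c0_g1 was at 0.961 CPM in replicate 1 and at 569 and 573 CPM in replicates 2 and 3, and TRINITY_DN11505_c0_g1 at 49.7, 671 and 391 CPM. The lower identifiers were TRINITY_DN14056_c0_g1, at 1.81 ± 0.672 CPM in SL against 14.2 ± 9.58 CPM (log2 difference -2.76, SE 0.292, edgeR adjusted p = 1.06e-05), and TRINITY_DN11340_c1_g1, at 1.095 ± 0.366 CPM against 8.02 ± 6.12 CPM (log2 difference -2.58, SE 0.277, edgeR adjusted p = 1.24e-05). Each of these log2 differences is taken against the mean of 4 log2 levels, so it is not the ratio of the mean CPM values. With the replicate number as a block 6847 genes passed, 4040 higher and 2807 lower. Against a fold change of 1.5 in place of no change, 1097 genes passed, and 2428 passed without SL replicate 2.

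ET differed from the mean of the other 4 compartments in 7138 genes, the most of the 5 compartments, with 3487 higher and 3651 lower. TRINITY_DN3934_c0_g2 stood at 1331 ± 71.5 CPM in ET (SD, n = 3) and at 722 ± 34.7 CPM in LT, against 34.2 ± 35.7 in SL, 6.66 ± 5.61 in TTJ and 0.762 ± 1.23 in BHTB. Its log2 difference was 6.28 (SE 0.556, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.4e-05). TRINITY_DN298_c0_g2 was at 677 ± 97.5 CPM in ET, 158 ± 37.6 in LT and 0.3 ± 0.306 in BHTB (log2 difference 4.96, SE 0.224, edgeR adjusted p = 3.98e-09). On the lower side, TRINITY_DN1068_c0_g1 had 3 counts in the ET libraries together and 707 in the 12 others, which were 90.7-fold higher relative to library size (95% exact counting interval 30.9 to 441; edgeR adjusted p = 0.00689). Leaving out 1 library gave ratios from 61.4 without ET replicate 2 to 139 without ET replicate 3. The ratio was 64.8 without SL replicate 1, which held 227 of the 707 counts. TRINITY_DN2944_c1_g1 was at 0.362 ± 0.499 CPM in ET against 21.1 ± 20.6 CPM (log2 difference -5.89, SE 1.09, edgeR adjusted p = 0.00215). Against a fold change of 1.5, 3255 genes passed. Without ET replicate 1, 2 or 3, BHTB gave more genes than ET, with 6976, 6540 and 6523 against 6505, 5005 and 4940. Without the filter on low counts, 4900 genes were higher and 2660 lower in ET, a share of 64.8% higher against 48.9%. The call of TRINITY_DN1068_c0_g1 was lost without the filter on low counts and without ET replicate 3.

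LT gave the fewest calls against the mean of the other 4 compartments, 2536 genes, of which 1650 were higher and 886 lower. TRINITY_DN3117_c0_g2 reached 819 ± 85.1 CPM in LT (SD, n = 3) and 291 ± 25.0 CPM in ET, and stood at 20.1 ± 2.21 in SL, 21.3 ± 6.31 in TTJ and 0.524 ± 0.462 in BHTB (log2 difference 5.73, SE 0.185; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.3e-11). TRINITY_DN23031_c0_g1 likewise had its highest mean in LT, at 259 ± 49.9 CPM, and its next in ET, at 167 ± 55.9 CPM. Its edgeR adjusted p of 2.1e-08 is for LT against the mean of the other 4 compartments and does not test LT against ET. The log2 difference of TRINITY_DN23031_c0_g1 is left out because the BHTB libraries held 0 counts of it. TRINITY_DN40854_c0_g3 was lower in LT, at 0.429 ± 0.0645 CPM against 9.25 ± 7.66 CPM over the 12 other libraries (log2 difference -3.80, SE 0.338, edgeR adjusted p = 1.21e-06). TRINITY_DN4517_c0_g1 was at 0.538 ± 0.302 CPM against 6.83 ± 3.22 CPM (log2 difference -3.46, SE 0.356, edgeR adjusted p = 6.57e-06). The count of genes was 4687 with the replicate number as a block (2981 higher, 1706 lower), 850 against a fold change of 1.5, 1623 without LT replicate 2 and 1391 without LT replicate 3. TTJ gave fewer genes than LT without the filter on low counts (2923 against 3419) and without TTJ replicate 2 (1980 against 2273).

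TTJ against the mean of the other 4 compartments gave 3529 genes, 2293 higher and 1236 lower. The named identifiers that rose most in TTJ had their next highest means in BHTB. TRINITY_DN31199_c1_g2 was at 15.7 ± 2.83 CPM in TTJ (SD, n = 3) and 10.1 ± 2.24 CPM in BHTB, against 3.08 ± 1.30 in SL, 0.226 ± 0.211 in ET and 0.15 ± 0.046 in LT (log2 difference 3.98, SE 0.253; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.9e-07). TRINITY_DN14309_c0_g1 was at 13.7 ± 0.194 CPM in TTJ and at 12.4 ± 0.763 CPM in BHTB (log2 difference 2.28, SE 0.225, edgeR adjusted p = 1.13e-05). TRINITY_DN4129_c0_g2 fell to 6.5 ± 2.54 CPM against 73.8 ± 71.9 CPM over the 12 other libraries (log2 difference -2.87, SE 0.535, edgeR adjusted p = 0.00466). TRINITY_DN12675_c1_g1 fell to 10.3 ± 4.48 CPM against 88.4 ± 59.9 CPM (log2 difference -2.87, SE 0.337, edgeR adjusted p = 0.000128). The count of genes was 5446 with the replicate number as a block (3389 higher, 2057 lower), 940 against a fold change of 1.5 and 1980 without TTJ replicate 2.

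BHTB differed from the mean of the other 4 compartments in 6726 genes, 3616 higher and 3110 lower. TRINITY_DN23031_c0_g1 and TRINITY_DN9400_c0_g3 had 0 counts in all 3 BHTB libraries. Over the 12 other libraries they had 14391 and 9438 counts, with mean CPM values at least 816-fold and 651-fold higher than a floor of 3 counts over the BHTB libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.32e-08 and 3.15e-06). TRINITY_DN9400_c0_g3 was at 172 ± 51.3 CPM in ET, 116 ± 36.2 in SL, 71.1 ± 29.6 in TTJ and 11.9 ± 4.59 in LT (SD, n = 3). TRINITY_DN122_c1_g3 was at 19.2 ± 9.86 CPM in BHTB against 1.46 ± 2.70 CPM over the 12 other libraries (log2 difference 5.47, SE 0.43, edgeR adjusted p = 3.46e-07). TRINITY_DN6764_c0_g1 was at 67.3 ± 46.4 CPM against 4.23 ± 7.26 CPM (log2 difference 5.41, SE 0.487, edgeR adjusted p = 8.95e-06). TTJ was the next highest compartment for both, at 5.02 ± 3.79 and 13.8 ± 10.1 CPM. In ET they were at 0.03 ± 0.052 and 0.219 ± 0.283 CPM, where 3 counts over the ET libraries make 0.087 CPM. Their log2 differences, taken against the mean of 4 log2 levels, rest partly on these low values, and their size is uncertain. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Against a fold change of 1.5, 3030 genes passed.

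**Figure D2:**
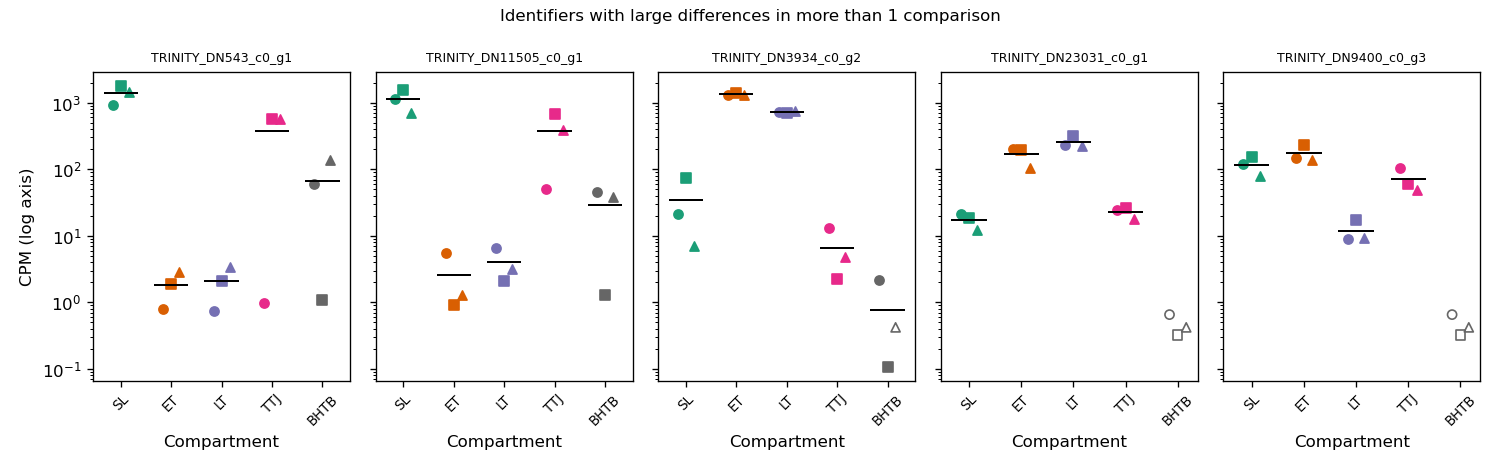
Normalised level (CPM, log axis) of the identifiers that the naming rule selected in more than 1 comparison, with 1 point per library, shape for the replicate number, and a bar at the mean of 3 libraries. An open symbol stands for 0 counts and is drawn at the level of 3 counts in that library. TRINITY_DN23031_c0_g1 and TRINITY_DN9400_c0_g3 have 0 counts in each BHTB library, and TRINITY_DN543_c0_g1 lies at 0.961 CPM in TTJ replicate 1 and at 569 and 573 CPM in TTJ replicates 2 and 3.

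Genes that exceeded each of the other 4 compartments in its own pairwise test numbered 491. SL held 165 of them, LT 118, ET 116, BHTB 91 and TTJ 1. The 1 for TTJ, chosen after its values were seen, was TRINITY_DN1351_c0_g1, at 80.8 ± 9.24 CPM in TTJ against 58.2 ± 1.67 in SL and 37.1 ± 4.71 in ET (SD, n = 3), with log2 differences from 0.47 (SE 0.153, edgeR adjusted p = 0.0476, SL) to 1.13 (SE 0.154, edgeR adjusted p = 4.44e-05, ET). Genes below each other compartment were most frequent for BHTB (365) and ET (219), followed by LT (67), SL (20) and TTJ (16). The total of 491 was 1419 with the replicate number as a block, 240 for isoform identifiers, 269 without ET replicate 2 and 268 without ET replicate 3. The block gave 392 for SL, 385 for ET, 327 for LT, 297 for BHTB and 18 for TTJ, and isoform identifiers gave 79, 54, 59, 48 and 0. For SL, 92, 81, 78 and 81 genes passed without ET replicate 2, ET replicate 3, SL replicate 1 and SL replicate 2. For ET, 38, 51, 67 and 70 genes passed without ET replicate 2, ET replicate 3, LT replicate 2 and SL replicate 1. For LT, 64, 62, 63 and 61 genes passed without ET replicate 2, ET replicate 3, LT replicate 2 and LT replicate 3. For BHTB, 30, 45, 53 and 33 genes passed without TTJ replicate 1, TTJ replicate 2, BHTB replicate 1 and BHTB replicate 2. For TTJ, 9 genes passed with DESeq2, 24 without the filter on low counts, 0 with thinned libraries, 13 without TTJ replicate 3, 3 without BHTB replicate 1, and 0 without ET replicate 2 or 3, LT replicate 1 or 3, SL replicate 2 or 3, TTJ replicate 1 or 2, or BHTB replicate 2 or 3.

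Sets of genes high or low in a pair of compartments showed TTJ with BHTB and SL with ET. These patterns were not among the tests fixed beforehand. In 591 genes both TTJ and BHTB exceeded each of the other 3 compartments, and in 498 both lay below them. SL and ET were both above the other 3 in 435 genes and both below in 586. ET and LT were both above in 209 genes and both below in 110, and LT and BHTB were both below in 94. With the replicate number as a block, these counts were 1072 and 813 for TTJ with BHTB, 817 and 1203 for SL with ET, and 358 and 210 for ET with LT. Without single libraries, TTJ with BHTB fell to 381 above (LT replicate 1), 366 above (TTJ replicate 2) and 301 below (TTJ replicate 2), and SL with ET to 347, 353 and 333 below (LT replicate 2, LT replicate 3, SL replicate 3). ET with LT fell to 67, 57, 72 and 67 below (ET replicate 2, ET replicate 3, LT replicate 3, SL replicate 2). Without the filter on low counts, TTJ with BHTB above fell to 348 and SL with ET above to 254. Isoform identifiers gave 270 for SL with ET above and 70 for ET with LT below.

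SL and TTJ, compared directly, differed in 4963 genes, 2418 higher and 2545 lower in SL. TRINITY_DN50809_c0_g1 was at 7.36 ± 6.62 CPM in SL (SD, n = 3) and 0.435 ± 0.754 CPM in TTJ (log2 difference 4.33, SE 1.21; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0325). In ET it was at 25.9 ± 14.3 CPM. TRINITY_DN3517_c0_g2 had 42 counts in SL and 2 in TTJ, 19.3-fold higher relative to library size in SL (95% exact counting interval 5.02 to 164; edgeR adjusted p = 0.0153). SL replicate 2 held 32 of the 42 counts, and the ratio was 6.74 without it and 30.5 without SL replicate 3. The identifier reached 71.9 ± 7.77 CPM in ET and 59.0 ± 9.33 CPM in LT. TRINITY_DN143431_c0_g1 was at 0.902 ± 0.464 CPM in SL against 13.6 ± 3.65 CPM in TTJ (log2 difference -4.00, SE 0.578, edgeR adjusted p = 0.000305). TRINITY_DN33066_c0_g1 was at 1.045 ± 0.322 CPM against 13.1 ± 10.6 CPM (log2 difference -3.66, SE 0.637, edgeR adjusted p = 0.0014). With the replicate number as a block 7495 genes passed (3756 higher, 3739 lower), and against a fold change of 1.5, 1899. The call of TRINITY_DN50809_c0_g1 was lost against that fold change, without the filter, and in the fit of the SL and TTJ libraries alone. It was also lost without SL replicate 1, SL replicate 3, TTJ replicate 1 or TTJ replicate 2. The call of TRINITY_DN3517_c0_g2 was lost without TTJ replicate 1 or TTJ replicate 2. In the fit of the SL and TTJ libraries alone, TRINITY_DN3517_c0_g2 had too few counts to pass the filter and was not tested.

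ET and SL differed in 1354 genes, 478 higher and 876 lower in ET. The identifiers with the largest falls were high in SL. TRINITY_DN543_c0_g1 was at 1.84 ± 1.03 CPM in ET against 1383 ± 426 CPM in SL (SD, n = 3; log2 difference -9.42, SE 2.07, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0304). TRINITY_DN11505_c0_g1 was at 2.56 ± 2.53 CPM against 1122 ± 417 CPM (log2 difference -8.99, SE 1.5, edgeR adjusted p = 0.00749). Higher in ET, TRINITY_DN3934_c0_g2 was at 1331 ± 71.5 CPM against 34.2 ± 35.7 CPM (log2 difference 5.29, SE 0.883, edgeR adjusted p = 0.00686). TRINITY_DN25381_c0_g1 had 295 counts in ET and 3 in SL, 52.5-fold higher relative to library size in ET (95% exact counting interval 17.8 to 256; edgeR adjusted p = 0.0213). ET replicate 3 held 228 of the 295 counts, and the ratio was 23.4 without it and 87.6 without SL replicate 3. With the replicate number as a block 2710 genes passed (1045 higher, 1665 lower), against a fold change of 1.5, 577, and without ET replicate 2, ET replicate 3, SL replicate 1 and SL replicate 2, 676, 671, 832 and 745. Calls were lost for TRINITY_DN543_c0_g1 against that fold change, without the filter and without any 1 library except SL replicate 3, for TRINITY_DN11505_c0_g1 without ET replicate 2 or ET replicate 3, and for TRINITY_DN25381_c0_g1 without any 1 SL library.

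LT and ET differed in 3523 genes, 2075 higher and 1448 lower in LT. TRINITY_DN9911_c0_g1 was at 106 ± 26.5 CPM in LT (SD, n = 3) and 6.67 ± 5.05 CPM in ET (log2 difference 4.03, SE 1.05; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0341). TRINITY_DN1408_c0_g1 was at 30.8 ± 20.4 CPM against 2.33 ± 1.13 CPM (log2 difference 3.83, SE 0.488, edgeR adjusted p = 0.00031). Both identifiers had their lowest mean in ET and neither had its highest in LT. TRINITY_DN9911_c0_g1 was at 150 ± 111 CPM in SL, 210 ± 110 in TTJ and 418 ± 444 in BHTB. TRINITY_DN1408_c0_g1 was at 15.2 ± 2.05 CPM in SL, 64.6 ± 16.8 in TTJ and 49.6 ± 13.0 in BHTB. Lower in LT, TRINITY_DN14725_c0_g2 was at 0.472 ± 0.158 CPM against 15.02 ± 6.27 CPM (log2 difference -5.00, SE 0.533, edgeR adjusted p = 3.24e-05). TRINITY_DN1107_c8_g1 was at 0.705 ± 0.332 CPM against 17.4 ± 2.22 CPM (log2 difference -4.62, SE 0.291, edgeR adjusted p = 1.66e-07). With the replicate number as a block 6465 genes passed (3789 higher, 2676 lower), against a fold change of 1.5, 1271, and without ET replicate 2, ET replicate 3, LT replicate 2 and LT replicate 3, 2040, 2128, 2225 and 2335. The call of TRINITY_DN9911_c0_g1 was lost without any 1 ET or LT library, without the filter and against that fold change.

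TTJ and BHTB had the fewest called genes of the 10 pairs, 659, with 525 higher and 134 lower in TTJ. The fit of the TTJ and BHTB libraries alone gave 297 higher and 149 lower, a share of 66.6% higher. TRINITY_DN9400_c0_g3 was at 71.1 ± 29.6 CPM in TTJ (SD, n = 3) with 1145 counts, at least 498-fold higher than the floor of 3 counts over the BHTB libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.1e-05). TRINITY_DN23031_c0_g1 was at 23.0 ± 4.396 CPM with 400 counts, at least 161-fold higher (edgeR adjusted p = 4.97e-06). Higher in BHTB, TRINITY_DN8990_c0_g1 was at 352 ± 114 CPM against 54.0 ± 31.8 CPM in TTJ (log2 difference TTJ minus BHTB -2.71, SE 0.552, edgeR adjusted p = 0.0295), and TRINITY_DN15486_c0_g2 at 264 ± 41.3 CPM against 44.6 ± 11.6 CPM (log2 difference -2.56, SE 0.397, edgeR adjusted p = 0.00346). Their means in SL, ET and LT were at most 14.3 CPM. With the replicate number as a block 1474 genes passed (898 higher, 576 lower, a share of 60.9% higher against 79.7%), against a fold change of 1.5, 321, and without TTJ replicate 1, BHTB replicate 1 and BHTB replicate 2, 426, 422 and 380. The call of TRINITY_DN8990_c0_g1 was lost without the filter, against that fold change, and without any 1 TTJ or BHTB library except TTJ replicate 3.

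**Figure D3:**
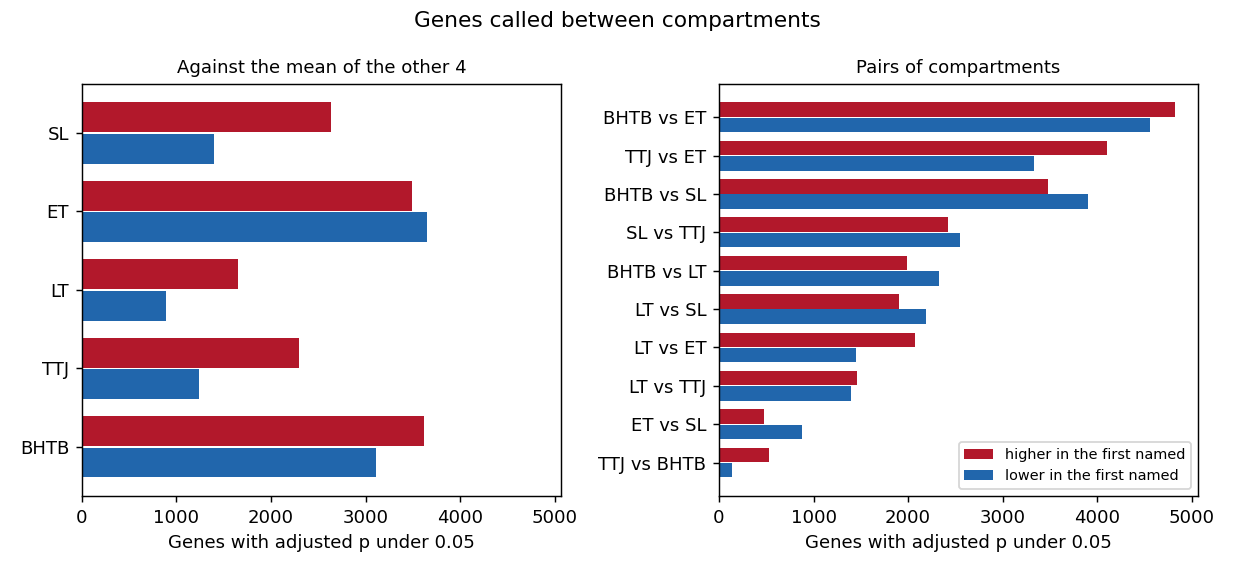
Bars give the number of genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, split into genes higher and lower in the compartment named first, for each compartment against the mean of the other 4 and for each of the 10 pairs. BHTB against ET has the most genes (9385) and TTJ against BHTB the fewest (659).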

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

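No alternative run on the named identifiers reversed the direction of one. Isoform identifiers were not run for them, and the thinning to equal depth was chosen after seeing the data. The call counts stayed within 1.5-fold for DESeq2, RLE scaling, no filter and thinning for any difference, each compartment against the mean of the others and the 4 pairs below, and for genes highest in 1 compartment except those in TTJ. The series matrix held the same values as the library tables, so it tested nothing. The gene lists, with camera, fry, an estimated correlation and their block, were not run because identifiers have no gene names. A replicate block raised the counts to 6847 genes for SL, 4687 for LT and 5446 for TTJ against the mean of the others, and to 7495 for SL versus TTJ, 2710 for ET versus SL, 6465 for LT versus ET and 1474 for TTJ versus BHTB. For pairs that were plotted only, it raised LT versus SL from 4091 to 7353, LT versus TTJ from 2858 to 4976 and BHTB versus LT from 4323 to 6590. With this block, genes highest in 1 compartment numbered 1419 (SL 392, ET 385, LT 327, TTJ 18, BHTB 297), and it raised the pair patterns as given in the report, moved none of the counts for any difference, ET and BHTB by as much, and ended no call of a named identifier. A test against a fold change of 1.5, which asks for more than a difference from 0, left 1097 genes for SL, 3255 for ET, 850 for LT, 940 for TTJ and 3030 for BHTB against the mean of the others. It left 1899 for SL versus TTJ, 577 for ET versus SL, 1271 for LT versus ET and 321 for TTJ versus BHTB. For isoform identifiers, genes highest in 1 compartment numbered 240 (SL 79, ET 54, LT 59, TTJ 0, BHTB 48), where the test covers other features. Genes highest in TTJ numbered 9 with DESeq2, 24 without the filter and 0 after thinning, and the cause was not tested. Leaving out 1 library gave ranges of 9101 to 10620 for any difference, 2428 to 4464 for SL, 4940 to 7614 for ET, 1391 to 2682 for LT, 1980 to 3724 for TTJ and 4493 to 6976 for BHTB. The ranges were 3334 to 3965 for SL versus TTJ, 671 to 1496 for ET versus SL, 2040 to 3194 for LT versus ET and 380 to 590 for TTJ versus BHTB. Genes highest in 1 compartment ranged from 268 to 514 (SL 78 to 188, ET 38 to 140, LT 61 to 127, TTJ 0 to 13, BHTB 30 to 98). Fits of the 2 compartments alone gave 297 higher and 149 lower genes for TTJ versus BHTB and 460 and 553 for ET versus SL. Without the filter, the share of higher genes rose from 48.9% to 64.8% for ET and from 65.1% to 83.7% for LT, and the median log2 difference of all genes moved by -0.51 for SL, 0.41 for ET, 0.38 for LT and -0.57 for TTJ. The pair patterns without the filter gave 348 genes for TTJ with BHTB above and 254 for SL with ET above, and isoform identifiers gave 270 for SL with ET above and 70 for ET with LT below. Depth limited which identifiers were tested, since 309416 had too few counts to pass the filter.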

Other observations

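The tests of the replicate number on TRINITY_DN5236_c0_g1 and of a batch on gene levels were chosen only after the result was seen, as were thinning and the assignments within replicate numbers. By the rule that follows, identifiers at 0 counts in 1 compartment alone were found only for BHTB. That rule was not among those fixed before the data were examined. With at least 1 CPM required in each of the 12 other libraries, 6 identifiers had 0 counts in the 3 BHTB libraries and 0 identifiers did so for each of SL, ET, LT and TTJ. A total of 2 of the 6 had at least 5 CPM in each other library, TRINITY_DN23031_c0_g1 with at least 12.01 CPM (mean 117) and TRINITY_DN9400_c0_g3 with at least 9.08 CPM (mean 93.0). The longest isoform of TRINITY_DN9400_c0_g3 has 253 bases, and identifiers of a cluster can share reads, so its transcript need not be absent. The floor of 3 counts over the group was 0.143 CPM in BHTB, against 0.178 in TTJ, 0.163 in SL, 0.09 in LT and 0.087 in ET.

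The libraries were reassigned at random to 5 groups of 3, with 60 assignments including the real one. For each of the 7 results below, 1 of the 60 reached the real count, the real assignment itself. That share is under 0.05, the limit set beforehand, among assignments that ignore the replicate number. It is the smallest share that 60 assignments can give, so it makes chance assignment of these libraries unlikely without excluding it. Chance differences between embryos were not tested, since the labels do not say which embryos the libraries came from. Any difference gave 10071 genes against at most 77 in the other assignments, SL 4036 against 5, ET 7138 against 1, TTJ 3529 against 214, BHTB 6726 against 71, and genes highest in 1 compartment 491 against 6. LT gave 2536 against 1662, from an assignment that kept the 3 BHTB libraries together as a group, which is a true compartment. A further 40 assignments, the real one included, kept 1 library of each replicate number in each group, and for each of the 7 results 1 of the 40, the real one, reached the real count. The highest of the others were 1511 for any difference, 2663 for SL, 1679 for ET, 16 for LT, 405 for TTJ, 58 for BHTB and 26 for genes highest in 1 compartment, with a median of 0 for each. In the fit with the replicate block they were 1485, 3054, 1603, 9, 254, 46 and 35, and again only the real assignment reached the real count. For pairs, 6 libraries allow 10 splits, too few for a share under 0.05. SL versus TTJ gave 4963 genes against at most 0 in the other splits, ET versus SL 1354 against 158, LT versus ET 3523 against 0 and TTJ versus BHTB 659 against 1, and 1 of the 10 splits, the real one, reached each count. Among the 4 splits that part all same-numbered pairs, the others gave at most 0.

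Libraries with the same replicate number shared isoforms across compartments. With at least 10 counts in all 5 libraries of 1 number and 0 counts in all 5 of another, 105 of 66009 isoforms were present or absent by number, against at most 43 and a median of 1 under the other numberings, and for 81 of the 90 in genes with several isoforms the gene sum stayed within 2-fold (median absolute log2 difference 0.22). A batch that only shifts levels had been predicted to leave no more such isoforms than the highest other numbering, 43, and the count was 105. That comparison cannot separate a batch from shared embryos, since the other numberings break up both. The gene sums argue against a shift of whole gene levels, but only for those 81 isoforms. In genes with 1 isoform the gene sum changes with the isoform, so it cannot tell. That same-numbered libraries came from the same embryos or pools of embryos remains a hypothesis for the pattern. Sequence variants assembled as separate isoforms would then follow the number. Whether a shared handling or library batch also contributes to gene levels, whose deviations correlated at a mean of 0.329 between same-numbered libraries, cannot be told apart from shared embryos, since the same numbers would carry both.

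TRINITY_DN5236_c0_g1 and 8 identifiers that track it at r above 0.95 across libraries, after removing compartment means, took between 0.859% of counts (ET replicate 2) and 9.52% (SL replicate 1). The ratios of the 8 to it varied over the libraries by CVs from 2.5% (TRINITY_DN20360_c0_g1) to 56.4% (TRINITY_DN19400_c0_g1). A single RNA source present in different amounts in the dissected pieces may account for this, but 8 trackers lie between the median (5) and the 95th percentile (28) over other abundant identifiers, which leaves that explanation open. For a difference that goes with the replicate number, 58.6% of the variance of TRINITY_DN5236_c0_g1 lay between numbers (exact permutation p = 0.0216, one-sided, over 1296 numberings). Gene levels in general deviated together by number, with a mean correlation of 0.329 between same-numbered libraries. That share need not be particular to this identifier, since the share of other identifiers was not computed. A difference between compartments did not pass edgeR's F-test for TRINITY_DN5236_c0_g1 (adjusted p = 0.135), which does not exclude one, and no other biological explanation was tested.

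ET and BHTB gave the most called genes against the mean of the others, and ET had the deepest library. In the fit with the replicate block, ET gave 9903 genes and BHTB 9418, against 6847 for SL, 4687 for LT and 5446 for TTJ. Without the block, the mean of the ET and BHTB counts was 2.06 times the mean of the SL, LT and TTJ counts. With all libraries thinned to 4322260 counts the ratio was 1.96, which argues against depth as the cause. The compartments themselves remain the open biological explanation, as a hypothesis, and the position of ET and BHTB at the ends of the first principal component is the same contrast and no independent evidence.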
